A study of Homo sapiens with 12 samples.

How the data were processed

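RNA was sequenced from MDA-MB-231 cells, a human triple-negative breast cancer line of epithelial origin that spreads aggressively when grown in mice. The labels place 12 samples in 4 groups of 3: control, hypoxia (low oxygen), oscillatory hypoxia (oxygen that goes up and down) and lactate, the acid that cells release when they ferment glucose. Oxygen levels, cycle length, lactate dose and treatment time are not given in the sources used here. Nothing in the labels says that the 3 samples of a group came from separate cultures, so each p-value measures only the spread between these samples, which may be technical.

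The authors deposited 1 table of TPM values (a transcript abundance: reads per gene divided by gene length and scaled to a fixed sum per sample), with 1 column per sample. Per the submitters' processing notes, HISAT2 and featureCounts were among the tools and GRCh38 was the genome build. The versions, gene annotation, filters, strand setting and way of computing TPM are not given in the sources used here. The table held 21408 rows with Ensembl identifiers. An identifier listed 2 times with equal values was kept once, which left 21407 genes. Of these, 1572 rows had no symbol, and 16 symbols were filled from a gene name table. In GENCODE release 29 (GRCh38), 21337 identifiers were found, and 92.9% of the genes were annotated as protein coding. All coordinates printed are from that release, 1-based.

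Low TPM values moved in steps, each worth 1 read. From those steps the relative depth of the samples and whole read numbers were recovered: in 99.3% of the 17077 genes above 0 in any sample, every value came out whole within 0.01 reads. Recovered reads per sample ranged from 16413909 to 23443323. These read numbers served to describe depth and the mitochondrial share of reads, to compare the replicates of a group with a chi-square test of their reads, to weigh depth as an explanation of a sample's values, and in 1 added alternative. In a gene of 10 kb, 1 read was worth 0.0399 to 0.0616 TPM. Counting error covers only part of the spread between samples.

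The steps also give the length by which each gene's reads were divided. Among tested genes with recovered reads, 97.0% had a length within 5% of the gene's whole span, introns included, in GENCODE release 29, and 3.6% a length within 5% of the gene's summed exons. The span was 5.63 times the summed exons in the median gene. TPM in this table is therefore low for genes with long introns, and levels of different genes cannot be ranked. The ratio of 1 gene's TPM between samples is not changed by its length. The filter at 1 TPM and the log2(TPM + 1) scale used below do depend on it. A gene with a long span can thus be left untested or have its change understated. A consequence for scaling is that the mitochondrial genes, which have no introns, took 17.6% to 29.6% of a sample's TPM but 1.5% to 3.0% of its reads, so the scale of all other genes moves with that share. Alternatives with other scalings were run for this reason.

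Some genes that every cell needs were listed at or near 0, among them RPS10, RPL32, RPL15 and NDUFA9. Their spans lie almost wholly inside other genes of the table. Of the 2140 genes with at least 95% of the span inside other genes on either strand, 98.3% had a mean below 1 TPM, against 48.5% of the 14035 genes with no such overlap. A gene at 0 is therefore described as listed at 0, and no statement is made on whether it was expressed. SLC16A3 has 67.5% and CA9 27.5% of the span inside other genes, and their values are uncertain for that reason. Genes with near-identical copies (KRTAP2-3 and KRTAP2-4, CGB5 and CGB8, HSPA1A and HSPA1B, MAGEA3, ALPP, the AKR1C genes, TRBV7-9 and the histone genes) are uncertain because reads can be split between copies.

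Values were transformed to log2(TPM + 1). Genes with a mean of at least 1 TPM over the 12 samples were tested, 10527 in all. limma 3.58.1 in R 4.3.3 was used with 1 mean per group, all 12 samples in the fit and a mean-variance trend in the moderated variances. Each gene thus had 1 residual variance shared by all groups. The median SD on the log2 scale was 0.195 in oscillatory hypoxia and 0.072 to 0.129 in the other groups. The p-values of oscillatory hypoxia can therefore be too small, and those of lactate against hypoxia too large. Tests were two-sided with Benjamini-Hochberg adjustment over the tested genes of each comparison, at a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The 5 comparisons were each treatment against control, oscillatory hypoxia against hypoxia, and lactate against hypoxia. Standard errors (SE) are from the fit.

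The gene lists (31), the rule for named genes, the tests and all settings tried except those said to be added were fixed before the data were examined, and 27 lists had at least 3 tested genes. They were tested with camera (correlation between genes preset to 0.01), with camera using an estimated correlation, and with fry, adjusted over the lists of a comparison. Beside the number of members that passed over all genes stands the number adjusted over the list alone. No list passed camera with an estimated correlation in any comparison. A list of RNAs without a poly(A) tail had 0 of its 10 genes in the table. The marker lists for fibroblasts, leukocytes and endothelial cells had 2, 2 and 1 tested genes, too few for a list test.

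The genes named were chosen by a fixed rule: in each comparison, the 8 strongest rises and 8 strongest falls past the threshold with a mean of at least 5 TPM in the higher group, groups that do not overlap and a symbol that is not a clone name; up to 3 members of each described list that passed with the strongest change, or the most changed member where none passed; a panel of 12 genes tied to hypoxia and lactate; and the genes HIF1A and EPAS1. From these the text names a part, and some genes are not reported here. Genes outside the rule were chosen after their values were seen. They are HSPA5, when set against control, HSPA1A, HSPA1B, DNAJB1 and HMOX1 among stress genes, PTPRC, CD163 and COL3A1 among markers of other cells, RPS10, RPL32, RPL15, NDUFA9, SDHA and CDKN2A among genes listed at or near 0, and MAGEB2 and SCG2 among genes that stood apart in oscillatory hypoxia.

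The fit was tested on simulated values with the real means and the residual spread pooled over groups, in which 200 of 10527 genes were changed. The simulated noise was independent between genes and equal in all groups. In the data the median SD on the log2 scale was 0.072 in lactate and 0.195 in oscillatory hypoxia. The rates below may therefore not hold for the real comparisons. For hypoxia against control, 94% of 2-fold and 57% of 1.41-fold changes were recovered, and 4.43% of calls were false. For oscillatory hypoxia against control these were 92%, 48% and 2.78%. For lactate against control they were 92%, 54% and 7.59%. For oscillatory hypoxia against hypoxia they were 90%, 52% and 4.7%, and for lactate against hypoxia 93%, 46% and 4.79%.

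The alternatives planned were a pseudocount of 0.1 or 5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, a fit on only the 2 groups compared, the replicate number as a block, no variance trend, robust variances, an added 2-fold limit and leaving out each sample. Added after seeing the data were limma's voom on the recovered reads, sample weights, TPM rescaled without mitochondrial genes, and list tests without hypoxia replicate 3 or oscillatory hypoxia replicate 3. Shared responses were set against 100 simulated sets of unchanged groups drawn from the residuals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.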

Results

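The transcriptome of MDA-MB-231 breast cancer cells was measured in 12 samples, 3 each from control, hypoxia, oscillatory hypoxia and lactate cultures. The series title poses the question of what each of these 3 conditions does to the cells. Values are TPM, given as mean ± SD of the 3 samples of a group (n = 3) unless stated otherwise. Recovered depth was 18228137, 19276833 and 23443323 reads in the control samples, 18839800, 22184559 and 16413909 in hypoxia, 17392170, 17016021 and 20339335 in oscillatory hypoxia, and 16464442, 20559843 and 19915192 in lactate.

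Hypoxia and lactate samples lay together on the first principal component, which held 47% of the variance, and the control samples lay at its other end with the oscillatory hypoxia samples closer to them. Replicates correlated across genes at 0.9951 or above within control, hypoxia and lactate. In oscillatory hypoxia the correlations were 0.9778 to 0.9897. The median SD of a gene on the log2 scale was 0.088 in control, 0.129 in hypoxia, 0.072 in lactate and 0.195 in oscillatory hypoxia. Between replicates of a group the chi-square per degree of freedom was 2.86 to 80.3, above read-counting noise, so no pair was merged, though repeat libraries of 1 culture could also differ by this much.

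**Figure D1:**
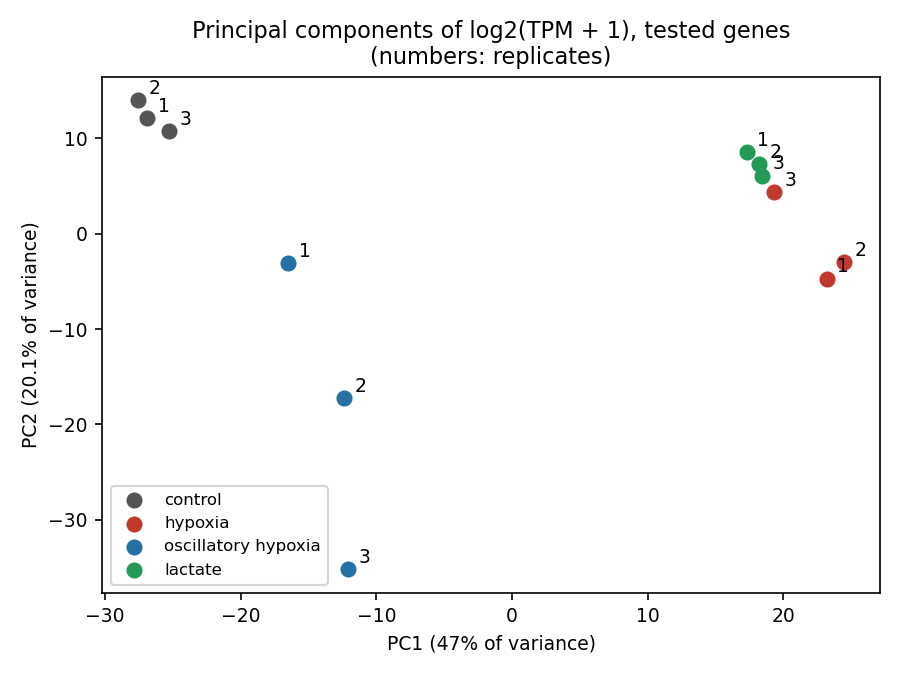
Principal components of log2(TPM + 1) over the 10527 tested genes, with 1 point per sample, the first component (47% of variance) on the x axis and the second (20.1%) on the y axis. Hypoxia and lactate samples lie between 17.3 and 24.5 on the first component, control samples between -27.6 and -25.3, and the oscillatory hypoxia samples between -16.5 and -12.1 with a wide spread on the second.

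Hypoxia against control addresses the response to steady low oxygen. Targets of hypoxia-inducible factor (HIF), the transcription factor that oxygen holds in check, rose together. ADM, which encodes the vasodilator peptide adrenomedullin (ENSG00000148926, chromosome 11, 10304680 to 10307397, GRCh38), rose from 188 ± 16.9 to 1090 ± 80.0 TPM (log2 fold change 2.54, SE 0.268, limma adjusted p = 1.53e-05). DDIT4, an inhibitor of mTORC1 signalling, rose from 1340 ± 113 to 3670 ± 222 TPM (adjusted p = 3.77e-05), and VEGFA, the angiogenic growth factor (ENSG00000112715, chromosome 6, 43770184 to 43786487), from 181 ± 11.1 to 496 ± 63.7 TPM (adjusted p = 0.000313). Of 27 measured HIF targets, 17 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 9.03e-06; adjusted p = 0.98 with an estimated correlation). CA9, the carbonic anhydrase that acidifies the cell surface (ENSG00000107159, chromosome 9, 35673856 to 35681159), rose from 17.3 ± 1.63 to 38.2 ± 3.83 TPM (adjusted p = 8.3e-05). NDRG1 rose by 1.36 (SE 0.112), BNIP3, a mitophagy receptor, by 0.58 (SE 0.0958) and KDM3A, a histone demethylase, by 0.82 (SE 0.128) on the log2 scale. EGLN3, an oxygen-sensing hydroxylase, was below the filter, at 0.722 ± 0.0761 TPM in control and 1.02 ± 0.0911 TPM in hypoxia. The messages of the HIF subunits themselves fell: HIF1A from 117 ± 5.74 to 71.5 ± 5.17 TPM (adjusted p = 0.000573) and EPAS1 from 16.8 ± 0.683 to 7.3 ± 0.335 TPM (adjusted p = 0.00145).

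**Figure D2:**
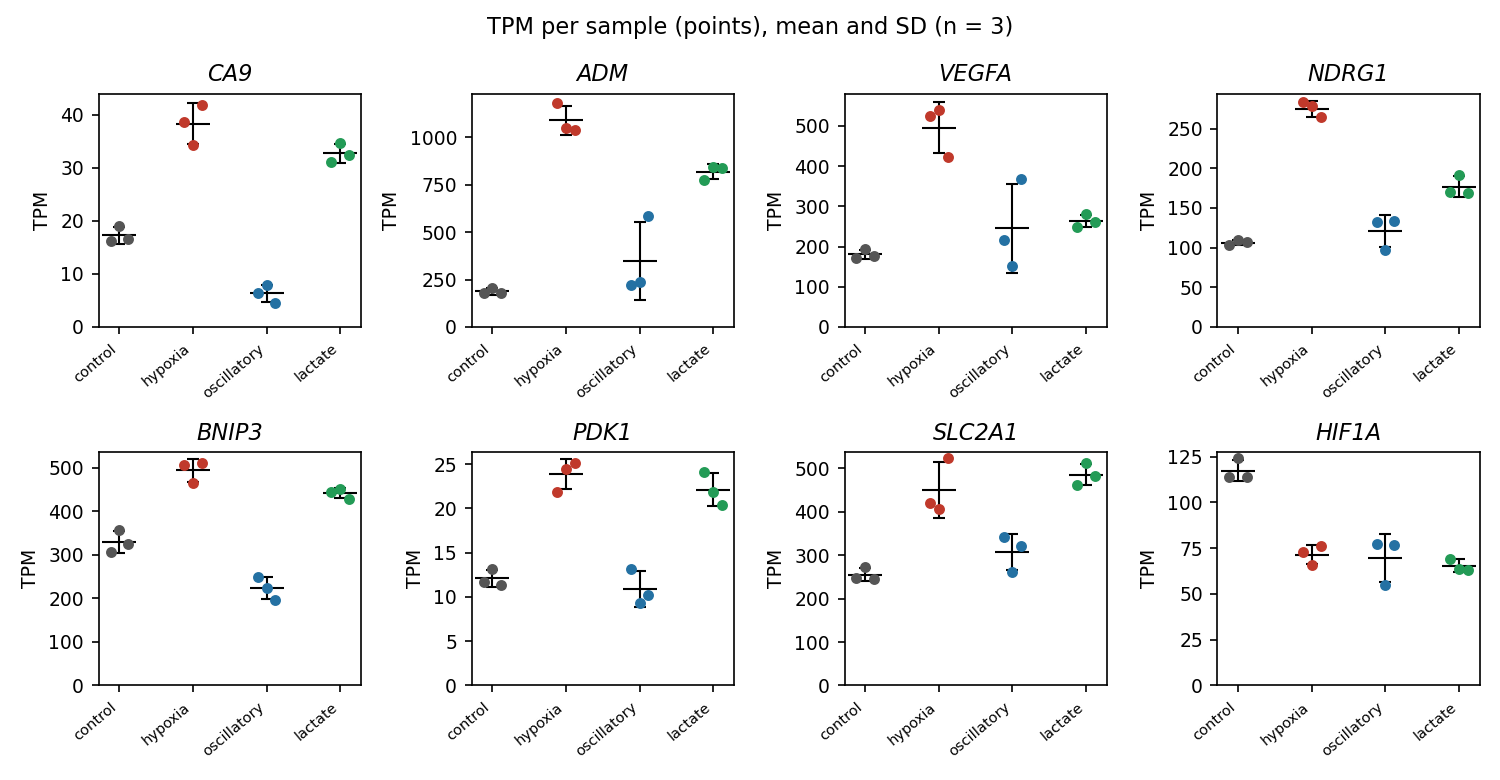
TPM of 7 HIF targets and of HIF1A in each sample (points), with the group mean and SD (bars, n = 3), the y axes being linear and starting at 0. ADM averaged 188 TPM in control, 1090 in hypoxia, 347 in oscillatory hypoxia and 819 in lactate, and CA9 lay below its control values in each oscillatory hypoxia sample.

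Glycolysis genes rose with the HIF targets. Of 20 measured, 12 rose and 1 fell (14 and 2 adjusted over the list alone; camera adjusted p = 1.1e-05; adjusted p = 0.98 with an estimated correlation). SLC2A3, a glucose transporter, rose from 16.5 ± 1.6 to 37.6 ± 3.45 TPM, PFKFB4 from 16.7 ± 1.38 to 34.4 ± 0.364 TPM and PDK1, a kinase that inhibits pyruvate dehydrogenase, from 12.1 ± 1.0 to 23.8 ± 1.67 TPM. The glucose transporter SLC2A1 rose by 0.81 (SE 0.118, adjusted p = 0.000169) and LDHA, which makes lactate from pyruvate, by 0.58 (SE 0.12, adjusted p = 0.00208). The lactate exporter SLC16A3 was at 254 ± 31.3 TPM against 278 ± 12.8 TPM (adjusted p = 0.392). LDHB was listed at 0.0179 to 0.0855 TPM over all 12 samples and could not be compared.

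Antioxidant genes fell in hypoxia. Of 25 measured members of the NRF2 and redox list, 16 fell and 2 rose (17 and 2 adjusted over the list alone; camera adjusted p = 9.99e-05; adjusted p = 0.98 with an estimated correlation). NQO1, a quinone reductase, fell from 190 ± 12.3 to 59.6 ± 10.5 TPM (adjusted p = 4.35e-07), and AKR1C2 from 7.0 ± 1.37 to 1.42 ± 0.302 TPM. TXNIP, a glucose-responsive inhibitor of thioredoxin, went the other way, from 280 ± 50.2 to 1090 ± 74.5 TPM (adjusted p = 0.000301). In the same samples the fibroblast list's PDGFRB fell from 5.13 ± 0.568 to 1.7 ± 0.815 TPM (adjusted p = 0.000153) and LUM from 2.83 ± 0.0765 to 1.79 ± 0.167 TPM (adjusted p = 0.0129, 0.118 after quantile normalization and 0.121 with voom). CD14, from the leukocyte list, fell from 50.7 ± 8.56 to 27.8 ± 5.21 TPM (adjusted p = 0.00179), and the endothelial marker EGFL7 was at 32.6 ± 5.87 against 40.4 ± 1.17 TPM (adjusted p = 0.0609). Of 6 measured luminal breast markers, 2 rose and 0 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.267, fry adjusted p = 0.0213; adjusted p = 0.98 with an estimated correlation). These were TFF1, a trefoil peptide gene, from 0.757 ± 0.562 to 6.91 ± 1.6 TPM (adjusted p = 8.48e-06), and the keratin gene KRT19, from 952 ± 84.8 to 1370 ± 64.1 TPM (adjusted p = 0.00086). DNA replication genes fell in 17 of 33 measured and rose in 0 (21 and 0 adjusted over the list alone; camera adjusted p = 0.000738; adjusted p = 0.98 with an estimated correlation). The replicative helicase gene MCM6 fell from 40.3 ± 3.66 to 17.7 ± 2.9 TPM.

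Cytosolic ribosomal protein genes rose in 14 of 62 and fell in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 1.45e-06; adjusted p = 0.98 with an estimated correlation), RPL10A by 0.55 (SE 0.0929) on the log2 scale. Of 21 genes of the ATF4 and amino acid response, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00219; adjusted p = 0.98 with an estimated correlation). The amino acid transporter SLC7A5 rose from 390 ± 19.3 to 839 ± 191 TPM, and PPP1R15A, which restores translation after stress, from 273 ± 25.5 to 916 ± 93.4 TPM. Immediate early genes rose in 11 of 26 and fell in 2 (12 and 4 adjusted over the list alone; camera adjusted p = 0.00219; adjusted p = 0.98 with an estimated correlation), among them ZFP36 and KLF10. After quantile normalization these last lists no longer passed (camera adjusted p = 0.0608 for ATF4, with a range of 3.36e-06 to 0.0608 over the alternatives, and 0.0772 for immediate early genes, with a range of 3.38e-05 to 0.0772). The remaining lists did not pass camera. Interferon response genes fell in 11 of 23 and rose in 1 (the same counts adjusted over the list alone; camera adjusted p = 0.0511, fry adjusted p = 0.00375), and extracellular matrix genes fell in 18 of 36 and rose in 5 (19 and 6 adjusted over the list alone; camera adjusted p = 0.232). The chaperone gene CALR fell from 4670 ± 451 to 1490 ± 144 TPM (adjusted p = 0.000117).

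Outside the lists, the strongest rise was in PRSS22, a serine protease gene, from 4.66 ± 1.36 to 58.3 ± 10.4 TPM (log2 fold change 3.40, SE 0.202, adjusted p = 3.16e-07). The amino acid transporter SLC38A5 rose from 2.41 ± 0.283 to 18.8 ± 0.949 TPM, and RNF223 from 2.3 ± 0.176 to 21.4 ± 3.33 TPM. TMEM89 was listed at 0 in all 3 control samples and at 6.07, 5.14 and 10.4 TPM in hypoxia. The strongest fall was in LGALS12, a galectin gene, from 19.1 ± 1.67 to 0.174 ± 0.0866 TPM (log2 fold change -4.09, SE 0.187, adjusted p = 9.01e-08). SLC7A4 fell from 37.6 ± 3.02 to 4.47 ± 1.46 TPM, the chemokine gene CX3CL1 from 22.6 ± 0.821 to 3.17 ± 1.07 TPM and the membrane metalloprotease gene MMP15 from 29.6 ± 0.958 to 4.59 ± 0.78 TPM.

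In all, 1470 genes were higher and 2934 lower in hypoxia, 144 and 395 of them by at least 2-fold. Groups did not overlap in 58% of genes, where chance gives 10%. With median-of-ratios scaling the counts were 2542 and 2699, so that the share of higher calls moved from 33.4% to 48.5%, and after quantile normalization it was 52.5%. Quantile normalization also moved the median log2 change of all genes from -0.09 to 0.02.

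Lactate against control addresses the response to lactate. Many of the same genes moved as in hypoxia. ADM rose from 188 ± 16.9 to 819 ± 39.7 TPM (log2 fold change 2.12, SE 0.268, adjusted p = 7.74e-05), CA9 from 17.3 ± 1.63 to 32.7 ± 1.85 TPM (adjusted p = 0.000513), and NDRG1 from 106 ± 3.16 to 177 ± 13.2 TPM (adjusted p = 0.000342). Of 27 HIF targets, 12 rose and 4 fell (12 and 5 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0642), though it did without oscillatory hypoxia replicate 3 (0.0204, with a range of 0.0204 to 0.22 over the alternatives). Those that fell included CA12, a carbonic anhydrase, and PLOD2, a collagen lysyl hydroxylase, which fell from 36 ± 2.13 to 18.3 ± 1.51 TPM. VEGFA was at 264 ± 15.4 against 181 ± 11.1 TPM (adjusted p = 0.0796). Glycolysis genes rose in 10 of 20 and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.00155; adjusted p = 0.931 with an estimated correlation). SLC2A1 rose from 255 ± 15 to 486 ± 24.5 TPM, LDHA from 2030 ± 130 to 3170 ± 108 TPM and PDK1 from 12.1 ± 1.0 to 22.1 ± 1.9 TPM. BNIP3 rose by 0.42 (SE 0.0958) and KDM3A by 0.53 (SE 0.128). SLC16A3 was at 243 ± 22.5 TPM (adjusted p = 0.213) and EGLN3 at 0.795 ± 0.0297 TPM. HIF1A fell to 65.4 ± 3.37 TPM and EPAS1 to 6.96 ± 0.233 TPM.

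Ribosomal protein genes rose in 38 of 62 and fell in 0 with lactate (43 and 0 adjusted over the list alone; camera adjusted p = 2.94e-09; adjusted p = 0.931 with an estimated correlation), RPL10A and RPL11 by 0.55 and 0.51 on the log2 scale. Genes of ribosome biogenesis rose in 13 of 27 and fell in 1, also adjusted over the list alone (camera adjusted p = 0.0309, 0.0522 after quantile normalization, 0.0192 to 0.0522 over the alternatives; adjusted p = 0.931 with an estimated correlation). Among them ODC1, the first enzyme of polyamine synthesis, rose from 140 ± 16.7 to 325 ± 20 TPM, and the gene that fell was MYC, from 228 ± 13.9 to 162 ± 11.1 TPM. MYC lost its call without control replicate 2 (adjusted p = 0.056) or lactate replicate 1 (adjusted p = 0.0592). Mitotic genes rose in 7 of 24 and fell in 1 (1 and 1 adjusted over the list alone; camera adjusted p = 0.0337, 0.118 after quantile normalization, 0.00275 to 0.118 over the alternatives; adjusted p = 0.931 with an estimated correlation), with PLK1 at 192 ± 3.97 against 123 ± 9.35 TPM.

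Antioxidant genes fell here too, in 18 of 25 with 2 that rose, also adjusted over the list alone (camera adjusted p = 2.02e-05; adjusted p = 0.931 with an estimated correlation). NQO1 fell from 190 ± 12.3 to 67.9 ± 1.61 TPM. Interferon response genes fell in 12 of 23 and rose in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 0.00155; adjusted p = 0.931 with an estimated correlation), with IFI6 at 9.64 ± 1.2 against 22.7 ± 1.09 TPM. In the same samples PDGFRB fell from 5.13 ± 0.568 to 2.34 ± 0.105 TPM (adjusted p = 0.00194) and CD14 from 50.7 ± 8.56 to 35 ± 1.77 TPM (adjusted p = 0.033), while LUM rose from 2.83 ± 0.0765 to 4.21 ± 0.567 TPM (adjusted p = 0.0195). The CD14 call was lost without control replicate 1 or 2 (0.0645 and 0.136), without lactate replicate 1, 2 or 3 (0.0846, 0.0585 and 0.0907), without a filter (0.0739) and with voom (0.059). The LUM call was lost without control replicate 1 (0.0622), without lactate replicate 1 or 2 (0.0578 and 0.0868) and with voom (0.0695). EGFL7 was at 36.2 ± 4.38 TPM (adjusted p = 0.34). Of the 6 luminal markers, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.497, fry adjusted p = 0.0472; adjusted p = 0.931 with an estimated correlation). TFF1 rose from 0.757 ± 0.562 to 8.45 ± 0.975 TPM (adjusted p = 4.52e-06), and XBP1, a transcription factor gene that is also in the ER chaperone list, fell from 143 ± 14.2 to 76.6 ± 6.16 TPM (adjusted p = 0.00157). Of 18 genes for chaperones of the endoplasmic reticulum (ER), 6 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0263; adjusted p = 0.931 with an estimated correlation). CALR fell from 4670 ± 451 to 1680 ± 46.7 TPM (adjusted p = 0.00034). The strongest falls outside the lists were in LGALS12, to 0.313 ± 0.152 TPM, and MMP15, to 3.77 ± 0.218 TPM. HLA-DOA, an antigen presentation gene, fell from 26.9 ± 3.26 to 3.55 ± 1.02 TPM. The strongest rises included SLC38A5, to 17.5 ± 0.945 TPM, and TFF1.

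With lactate, 1806 genes were higher and 2124 lower, 110 and 303 of them by at least 2-fold. Groups did not overlap in 64.1% of genes, where chance gives 10%. Without control replicate 1 the number of higher genes was 1198. Higher genes outnumbered lower ones after quantile normalization (2726 and 2333), with sample weights (3863 and 3672) and without control replicate 2 (1638 and 1541).

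Oscillatory hypoxia against control asks what changing oxygen does, and the HIF targets did not rise as a list. CA9 fell from 17.3 ± 1.63 to 6.32 ± 1.66 TPM (log2 fold change -1.34, SE 0.146, adjusted p = 0.000127), BNIP3 from 329 ± 25.2 to 223 ± 25.3 TPM (adjusted p = 0.00206) and AK4, a mitochondrial adenylate kinase gene, from 23.6 ± 2.19 to 11.3 ± 2.23 TPM. Of 27 HIF targets, 9 fell and 0 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.114, fry adjusted p = 0.0438). ADM was at 219, 238 and 584 TPM in the 3 samples (adjusted p = 0.0759). VEGFA (245 ± 110 TPM, adjusted p = 0.32), NDRG1 (121 ± 20.1 TPM, adjusted p = 0.325), PDK1 (10.9 ± 2.03 TPM), SLC2A1 (308 ± 41.6 TPM), LDHA (1850 ± 322 TPM) and KDM3A (14.5 ± 3.27 TPM) did not pass. EGLN3 was at 0.815 ± 0.194 TPM. SLC16A3 fell by 0.42 on the log2 scale (adjusted p = 0.029), a call lost without control replicate 1, 2 or 3 (adjusted p = 0.0751, 0.103 and 0.065), without oscillatory hypoxia replicate 2 or 3 (0.0534 and 0.0761), without a filter, with sample weights and with only the 2 groups in the fit. Glycolysis genes fell in 5 of 20 and rose in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.347), ENO1 from 2240 ± 121 to 1610 ± 131 TPM. HIF1A fell to 69.5 ± 12.9 TPM (adjusted p = 0.00138), and EPAS1 was at 13.5 ± 6.15 TPM (adjusted p = 0.233).

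Inflammatory and interferon genes rose instead by camera. In oscillatory hypoxia against control fry passed only 3 lists, the HIF targets among them. Most lists that passed camera in this comparison therefore did not pass fry. Of 25 measured NF-kB targets and cytokines, 11 rose and 1 fell (15 and 3 adjusted over the list alone; camera adjusted p = 2.16e-08; adjusted p = 0.603 with an estimated correlation). The neutrophil chemokine gene CXCL1 rose from 203 ± 12.7 to 660 ± 125 TPM (adjusted p = 0.000178) and IL1A from 22.1 ± 2.14 to 52.2 ± 12.3 TPM (adjusted p = 0.000529). Interferon response genes rose in 7 of 23 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 1.14e-05; adjusted p = 0.603 with an estimated correlation). OASL rose from 3.55 ± 0.536 to 13.1 ± 1.8 TPM (adjusted p = 1.65e-05) and ISG15 from 63.9 ± 2.66 to 147 ± 29.4 TPM (adjusted p = 0.000172). Without replicate 3 the counts were 11 and 1 for the first list and 8 and 1 for the second. In the same samples CD14, from the leukocyte marker list, rose from 50.7 ± 8.56 to 102 ± 22.9 TPM and CD68 from 545 ± 43.8 to 718 ± 43.9 TPM (a call lost with only the 2 groups in the fit, adjusted p = 0.0607), while PTPRC did not exceed 0.06 TPM and CD163 was listed at 0 in every sample. LUM, from the fibroblast list, rose from 2.83 ± 0.0765 to 7.25 ± 1.6 TPM and PDGFRB fell from 5.13 ± 0.568 to 2.73 ± 0.613 TPM (adjusted p = 0.0147, 0.0631 without control replicate 1), while COL3A1 did not exceed 0.05 TPM. PTPRC, CD163 and COL3A1 were chosen after their values were seen. The endothelial marker EGFL7 was at 30.6 ± 2.71 against 40.4 ± 1.17 TPM (adjusted p = 0.0484), a call lost in most alternatives, among them without control replicate 1, 2 or 3 (adjusted p = 0.105, 0.124 and 0.124), without oscillatory hypoxia replicate 2 or 3 (0.054 and 0.113), and without hypoxia replicate 1 or lactate replicate 2 or 3 (0.0634, 0.0633 and 0.0653). Of the 6 luminal markers, 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.347, fry adjusted p = 0.814), with a mean log2 change of 0.1 and a median of -0.01, which was 0.08 after median-of-ratios scaling or quantile normalization. TFF1 was at 1.96 ± 0.596 against 0.757 ± 0.562 TPM (adjusted p = 0.0263), a call lost without control replicate 2 or 3 (0.113 and 0.094) or oscillatory hypoxia replicate 2 (0.0834), with a pseudocount of 5, without a filter, with sample weights and with only the 2 groups in the fit. ERBB3 was at 2.18 ± 0.686 against 3.28 ± 0.173 TPM (adjusted p = 0.0395). Its call was lost without a filter, with only the 2 groups in the fit, and without control replicate 1, 2 or 3 (0.125, 0.105 and 0.0787), oscillatory hypoxia replicate 2 (0.0697), hypoxia replicate 1 or 2 (0.0536 and 0.0531) or lactate replicate 1, 2 or 3 (0.0548, 0.0586 and 0.0563).

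Stress genes differed between the oscillatory hypoxia samples, replicate 3 standing apart. HSPA6, an inducible heat shock protein gene, was at 10.1, 19.9 and 1890 TPM in replicates 1, 2 and 3, against 1.93 ± 1.4 TPM in control (log2 fold change 4.81, SE 1.35, adjusted p = 0.0282). HSPA5, the main ER chaperone, chosen after its values were seen, was at 1930, 1950 and 13100 TPM, against 2130 ± 198 TPM in control, and CHAC1, which breaks down glutathione, at 28.9, 27.4 and 208 TPM, against 10.3 ± 1.78 TPM. ATF4 and amino acid response genes rose in 10 of 21 and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 6.91e-09; adjusted p = 0.844 with an estimated correlation). Without replicate 3 they rose in 9 and fell in 1 (camera adjusted p = 5.44e-09), and the median log2 change moved from 1.0 to 0.39. Heat shock genes rose in 4 of 16 and fell in 0, also adjusted over the list alone (camera adjusted p = 6.74e-05; adjusted p = 0.844 with an estimated correlation). Without replicate 3 these counts were again 4 and 0, with a median of 0.15 in place of 0.34. ER chaperone genes passed as a list (camera adjusted p = 0.00164; adjusted p = 0.854 with an estimated correlation) with 0 of 18 members past the threshold, and 0 adjusted over the list alone. Without replicate 3, 1 rose and 4 fell, the list pointed down and it did not pass (camera adjusted p = 0.686, with a range of 0.00075 to 0.686 over the alternatives). It did not pass after quantile normalization either (adjusted p = 0.0709). HSPA6 lost its call without control replicate 1, 2 or 3 (adjusted p = 0.0607, 0.0837 and 0.0876), and CHAC1 without control replicate 3 (adjusted p = 0.0554). Both lost it without a filter, with robust variances and with only the 2 groups in the fit, and HSPA6 also with a pseudocount of 5 (adjusted p = 0.0586) and with voom (adjusted p = 0.303).

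**Figure D3:**
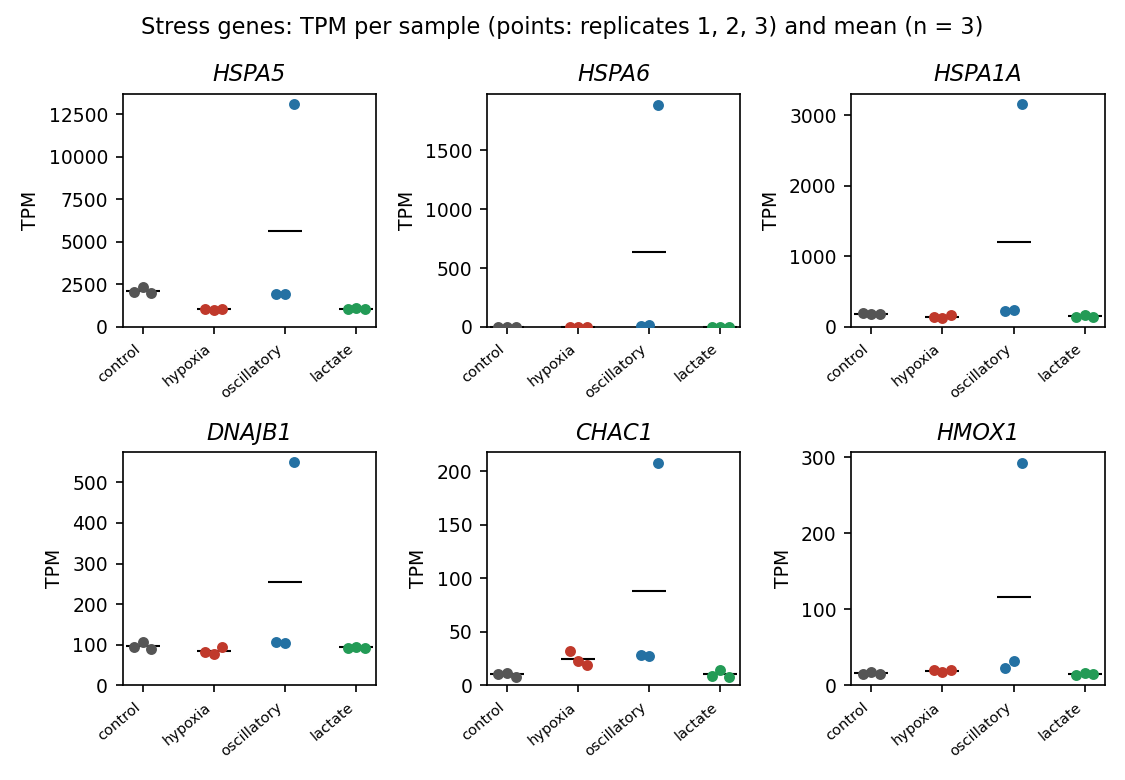
TPM of 6 stress genes, of which HSPA5, HSPA1A, DNAJB1 and HMOX1 were chosen after their values were seen, in each sample (points, replicates 1 to 3 from left to right) with the group mean (bar), the y axes being linear and starting at 0. In each of the 6 genes oscillatory hypoxia replicate 3 is the highest of the 12 samples, for example HMOX1 at 293 TPM against 23.6 and 32.2 TPM in the other replicates.

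Extracellular matrix genes fell in 14 of 36 and rose in 3 in oscillatory hypoxia (20 and 3 adjusted over the list alone; camera adjusted p = 0.00668; adjusted p = 0.854 with an estimated correlation), the laminin gene LAMA5 from 107 ± 3.54 to 43.2 ± 11.4 TPM. Mitotic genes fell in 3 of 24 and rose in 0 (14 and 0 adjusted over the list alone; camera adjusted p = 0.00105; adjusted p = 0.854 with an estimated correlation), and without replicate 3 in 1 (camera adjusted p = 0.131, with a range of 0.000354 to 0.131 over the alternatives). The 3 of 24 is close to the share over all tested genes, of which 1347 of 10527 were lower. CCNB1, the most changed of the 3, lost its call without control replicate 1, 2 or 3 (adjusted p = 0.0673, 0.1 and 0.057), without a filter and with only the 2 groups in the fit. The others, KIF20A and AURKA, stood closer to the threshold (limma adjusted p = 0.0339 and 0.0446, against 0.0263 for CCNB1). Genes of the respiratory chain rose in 3 of 44 and fell in 0 (2 and 0 adjusted over the list alone; camera adjusted p = 0.00504; adjusted p = 0.854 with an estimated correlation). The histone list also passed (3 of 12 rose and 1 fell, also adjusted over the list alone; camera adjusted p = 0.0236; adjusted p = 0.844 with an estimated correlation), though not after median-of-ratios scaling (adjusted p = 0.132, with a range of 0.025 to 0.132 over the alternatives), after quantile normalization (0.109) or without oscillatory hypoxia replicate 3 (0.116). Ribosome biogenesis genes rose in 3 of 27 and fell in 1 (0 and 0 adjusted over the list alone; camera adjusted p = 0.00704; adjusted p = 0.854 with an estimated correlation).

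The strongest rise after HSPA6 was in MSX1, a homeobox gene (ENSG00000163132, chromosome 4, 4859666 to 4863936), from 0.127 TPM or less in control to 6.37, 11.3 and 15 TPM (log2 fold change 3.40, SE 0.222, adjusted p = 4.84e-06). The calcium-binding gene S100A14 rose from 0.566 ± 0.813 to 10.1 ± 3.52 TPM (adjusted p = 0.000307). The cancer-testis antigen MAGEA3 was listed at 0 in every control and hypoxia sample and at 3.48, 4.98 and 10.5 TPM here (adjusted p = 4.6e-05). Falls included SEMA3B, a semaphorin gene, from 170 ± 4.75 to 58.1 ± 3.72 TPM (adjusted p = 6.68e-07), SPRY1, an inhibitor of growth factor signalling, from 18.3 ± 1.57 to 5.58 ± 0.265 TPM, and LGALS12, from 19.1 ± 1.67 to 2.83 ± 1.14 TPM.

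In oscillatory hypoxia 498 genes were higher and 1347 lower than in control, 64 and 89 of them by at least 2-fold. Groups did not overlap in 32.7% of genes, where chance gives 10%. With median-of-ratios scaling the counts were 1185 and 1377, the share of higher calls moving from 27% to 46.3%. With only the 2 groups in the fit the counts were 162 and 445. They were 208 and 677 without control replicate 1, 357 and 630 without control replicate 2 and 214 and 837 without control replicate 3, and 2434 genes were lower without oscillatory hypoxia replicate 1.

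**Figure D4:**
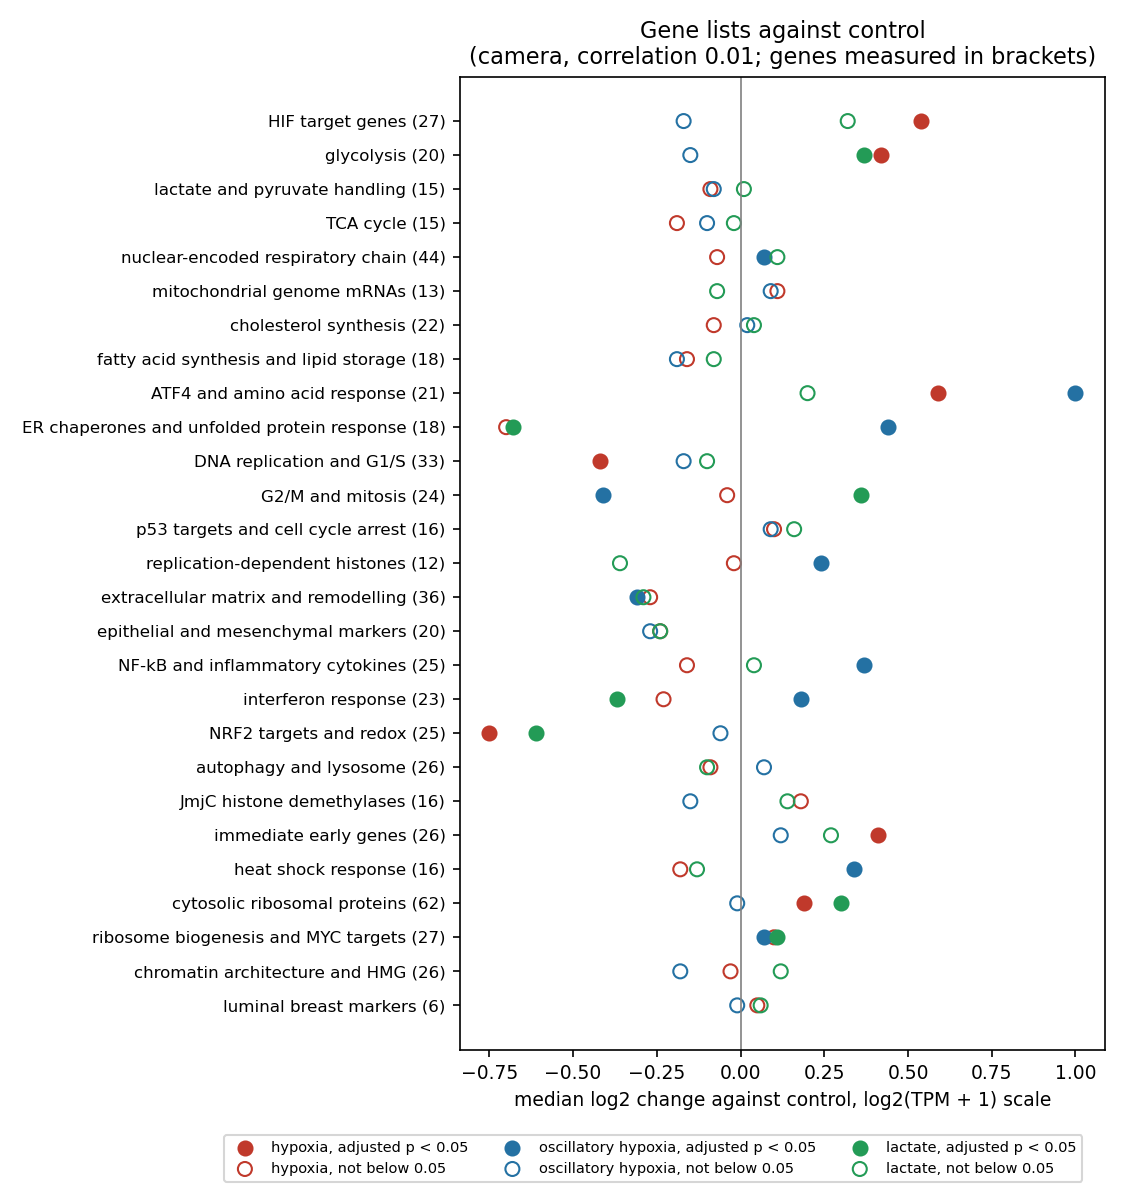
Median log2 change against control (x axis, log2(TPM + 1) scale) of each of 27 gene lists (y axis, tested genes in brackets) in hypoxia, oscillatory hypoxia and lactate, filled where camera with a preset correlation of 0.01 passed. The HIF targets lie at 0.54 in hypoxia, 0.32 in lactate and -0.17 in oscillatory hypoxia. No list passed with an estimated correlation.

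Oscillatory hypoxia was set directly against hypoxia. HIF targets were lower in 19 of 27 and higher in 2 (20 and 2 adjusted over the list alone; camera adjusted p = 3.78e-09, fry adjusted p = 9.23e-05; adjusted p = 0.386 with an estimated correlation). CA9 was at 6.32 ± 1.66 against 38.2 ± 3.83 TPM (log2 fold change -2.44, SE 0.146, adjusted p = 9.42e-07), DDIT4 at 738 ± 252 against 3670 ± 222 TPM (adjusted p = 3.62e-06) and BNIP3 at 223 ± 25.3 against 494 ± 25.9 TPM (adjusted p = 8.29e-06). ADM, VEGFA, NDRG1 and KDM3A were lower by a log2 fold change of -1.80, -1.10, -1.19 and -0.94. Glycolysis genes were lower in 14 of 20 and higher in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 6.47e-08; adjusted p = 0.557 with an estimated correlation), with log2 fold changes of -1.42 for PFKFB4, -1.07 for PDK1, -0.73 for LDHA and -0.55 for SLC2A1. SLC16A3 (adjusted p = 0.0836) and HIF1A (adjusted p = 0.759) did not pass. EPAS1 was higher, at 13.5 ± 6.15 against 7.3 ± 0.335 TPM (adjusted p = 0.0246), a call lost without hypoxia replicate 1, 2 or 3 (adjusted p = 0.0713, 0.0573 and 0.0551), without a filter and with only the 2 groups in the fit.

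Interferon response genes were higher in oscillatory hypoxia than in hypoxia in 17 of 23 and lower in 0, also adjusted over the list alone (camera adjusted p = 3.78e-09; adjusted p = 0.234 with an estimated correlation), with IFI6 at 28.1 ± 5.33 against 9.37 ± 2.09 TPM. In the same samples CD14 was higher, at 102 ± 22.9 against 27.8 ± 5.21 TPM (adjusted p = 1.67e-05), as was LUM, at 7.25 ± 1.6 against 1.79 ± 0.167 TPM (adjusted p = 8.29e-06). PDGFRB was at 2.73 ± 0.613 against 1.7 ± 0.815 TPM (adjusted p = 0.0482), a call lost without hypoxia replicate 1 or 2 (0.178 and 0.175), oscillatory hypoxia replicate 1 (0.15), control replicate 1, 2 or 3 (0.0613, 0.0585 and 0.0646) or lactate replicate 1, 2 or 3 (0.0633, 0.064 and 0.0648). It was also lost with a pseudocount of 5 (0.0626), without a filter (0.0991) and with only the 2 groups in the fit (0.153). EGFL7 was at 30.6 ± 2.71 against 32.6 ± 5.87 TPM (adjusted p = 0.668). Of the 6 luminal markers, 3 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.314, fry adjusted p = 0.0218; adjusted p = 0.836 with an estimated correlation). TFF1 was at 1.96 ± 0.596 against 6.91 ± 1.6 TPM (adjusted p = 0.000432), KRT19 at 924 ± 86.4 against 1370 ± 64.1 TPM (adjusted p = 0.000941) and XBP1, which was higher, at 187 ± 59.6 against 106 ± 11.4 TPM (adjusted p = 0.00468). Antioxidant genes were higher in 16 of 25 and lower in 2 (20 and 2 adjusted over the list alone; camera adjusted p = 4.11e-06; adjusted p = 0.48 with an estimated correlation). NQO1 was at 135 ± 5.79 against 59.6 ± 10.5 TPM, while TXNIP was lower, at 246 ± 126 against 1090 ± 74.5 TPM. NF-kB targets and cytokines were higher in 15 of 25 and lower in 4 (16 and 4 adjusted over the list alone; camera adjusted p = 0.00301; adjusted p = 0.834 with an estimated correlation), CXCL8 at 568 ± 94.6 against 159 ± 27.3 TPM. DNA replication genes were higher in 12 of 33 and lower in 0, also adjusted over the list alone (camera adjusted p = 0.000384; adjusted p = 0.838 with an estimated correlation), and without replicate 3 in 24. ER chaperone genes were higher in 12 of 18 and lower in 0 (17 and 0 adjusted over the list alone; camera adjusted p = 1.3e-05; adjusted p = 0.834 with an estimated correlation), with and without replicate 3, though the median log2 difference was 1.11 with it and 0.6 without. Heat shock genes were higher in 9 of 16 and lower in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 1.98e-05; adjusted p = 0.783 with an estimated correlation), and HSPB1 was at 2200 ± 198 against 1070 ± 165 TPM.

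Ribosomal protein genes were lower in oscillatory hypoxia than in hypoxia in 13 of 62 and higher in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 1.98e-05; adjusted p = 0.838 with an estimated correlation), with RPL10A at 2490 ± 223 against 3510 ± 149 TPM. Mitotic genes were lower in 9 of 24 and higher in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00112; adjusted p = 0.838 with an estimated correlation). Without oscillatory hypoxia replicate 3 they were lower in 5 and higher in 3, and the list did not pass (camera adjusted p = 0.181, with a range of 0.00085 to 0.181 over the alternatives). JmjC histone demethylase genes, whose products need oxygen, were lower in 5 of 16 and higher in 0 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00677; adjusted p = 0.838 with an estimated correlation), with KDM4B at 4.76 ± 0.871 against 9.22 ± 0.583 TPM.

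Between these conditions 1747 genes were higher and 1458 lower in oscillatory hypoxia, 210 and 91 of them by at least 2-fold. Groups did not overlap in 35.2% of genes, where chance gives 10%. Lower genes outnumbered higher ones after quantile normalization (2037 higher and 2442 lower), without mitochondrial genes in the total (1797 and 1915), with voom (2118 and 2129), without oscillatory hypoxia replicate 1 (1460 and 1835) and without hypoxia replicate 2 (1143 and 1176). With only the 2 groups in the fit the counts were 832 and 591.

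Lactate was also set directly against hypoxia. The HIF target NDRG1 was lower with lactate, at 177 ± 13.2 against 275 ± 9.52 TPM (log2 fold change -0.64, SE 0.112, adjusted p = 0.0364), as was PRSS22, at 20.6 ± 2.67 against 58.3 ± 10.4 TPM (adjusted p = 0.0186). IGFBP1, a binding protein of insulin-like growth factors, was lower as well, at 26.6 ± 0.715 against 61.3 ± 8.83 TPM (adjusted p = 0.022). EDN1, the vasoconstrictor endothelin, was higher with lactate, at 24.6 ± 2.69 against 11.7 ± 3.13 TPM (adjusted p = 0.0186), and so was the Wnt inhibitor DKK1, at 876 ± 38.4 against 459 ± 152 TPM (adjusted p = 0.0394). LUM, from the fibroblast list, was higher with lactate as well, at 4.21 ± 0.567 against 1.79 ± 0.167 TPM (adjusted p = 0.0186). The luminal markers did not pass as a list (camera adjusted p = 0.213), their median log2 change being 0.12 and their mean -0.02. The HIF targets lay lower as a list (camera adjusted p = 1.59e-15, fry adjusted p = 0.189; adjusted p = 0.127 with an estimated correlation), with a median log2 change of -0.23 and with 1 of 27 members past the threshold (8 adjusted over the list alone). VEGFA was at 264 ± 15.4 against 496 ± 63.7 TPM (adjusted p = 0.145), and CA9, ADM, BNIP3, PDK1, SLC2A1, LDHA, KDM3A, SLC16A3, HIF1A and EPAS1 did not pass, with adjusted p from 0.348 to 0.909. Between lactate and hypoxia, 14 genes were higher and 23 lower, and 1497 had an unadjusted p below 0.05. Groups did not overlap in 26% of genes, where chance gives 10%. Counts were 51 and 122 with median-of-ratios scaling, 60 and 119 after quantile normalization, 96 and 143 with voom on recovered reads, 34 and 50 without mitochondrial genes in the total, 77 and 109 with only the 2 groups in the fit, and 3457 and 509 with sample weights. With limma 0 genes passed without lactate replicate 1, 2 or 3, where 942, 925 and 1011 had an unadjusted p below 0.05, or without hypoxia replicate 1 or 2, where 669 and 788 had. NDRG1 and DKK1 also lost their calls without control replicate 1, 2 or 3 (adjusted p = 0.069, 0.0696 and 0.0711 for NDRG1, and 0.0703, 0.076 and 0.0711 for DKK1), and DKK1 without oscillatory hypoxia replicate 1 (adjusted p = 0.0505). Without a filter 1 gene was higher and 0 lower, and 234 were higher and 40 lower without hypoxia replicate 3. They were 5 and 13, 7 and 14, and 6 and 12 without control replicates 1, 2 and 3, and 28 and 33, and 130 and 101, without oscillatory hypoxia replicates 2 and 3.

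In the same comparison of lactate with hypoxia, the other 11 lists that passed camera had 0 members past the threshold in limma. DNA replication genes had a median log2 change of 0.39 (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.58e-08; adjusted p = 0.771 with an estimated correlation), and the histone genes of -0.33 (0 and 3 adjusted over the list alone; camera adjusted p = 8.27e-06; adjusted p = 0.127 with an estimated correlation). Mitotic genes had a median of 0.34 (camera adjusted p = 6.58e-05; adjusted p = 0.806 with an estimated correlation), ATF4 and amino acid response genes of -0.28 (camera adjusted p = 1.05e-05; adjusted p = 0.771 with an estimated correlation) and immediate early genes of -0.15 (camera adjusted p = 1.97e-05; adjusted p = 0.771 with an estimated correlation), each with 0 adjusted over the list alone. Medians were -0.05 for glycolysis genes (camera adjusted p = 0.00125), -0.01 for interferon response genes (0.0033) and -0.02 for JmjC demethylase genes (0.00305, the median being 0.02 without hypoxia replicate 3), with an adjusted p = 0.771, 0.771 and 0.806 with an estimated correlation and 0, 1 and 0 members adjusted over the list alone. Mitochondrial genome mRNAs (-0.18, camera adjusted p = 0.000348) did not pass after quantile normalization (0.727), nor respiratory chain genes (0.13, 0.00707) after median-of-ratios scaling (0.096). Ribosomal protein genes (0.12, 0.0367) did not pass after median-of-ratios scaling (0.546) or without oscillatory hypoxia replicate 3 (0.089). These last lists had 0 members adjusted over the list alone, and an adjusted p = 0.771, 0.806 and 0.806 with an estimated correlation. Fry passed no list in this comparison.

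The responses to the treatments were compared across the 10527 genes, which are not independent replicates. Hypoxia and lactate fold changes against control had a Pearson correlation of 0.91, where unchanged groups set against shared controls gave 0.47 on average and up to 0.92. Their covariance was 0.203 against a simulated 0.012. They shared 1205 higher and 1932 lower genes, where independent lists of those sizes would share 252 and 592, and 1 gene went opposite ways. For hypoxia and oscillatory hypoxia the correlation was 0.55 (simulated 0.5 on average and up to 0.94), the covariance 0.09 (simulated 0.013), and 281 higher and 922 lower genes were shared, where 70 and 375 would be by independence. In that pair 60 genes were called in opposite directions, among them CA9 and BNIP3, which rose in hypoxia and fell in oscillatory hypoxia. For oscillatory hypoxia and lactate the covariance was 0.08 (simulated 0.012) and the correlation 0.52 (simulated 0.45 on average and up to 0.95). The 3 control samples cannot be split so that each part keeps at least 2, so part of each excess may come from the shared controls, which the numbers expected by independence leave out.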

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

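The gene lists and their tests were planned, while the rule that picks lists out below and the tests of explanations were chosen after the result was seen. Gene lists are reported here when their median change against control had opposite signs in hypoxia and oscillatory hypoxia and the direct comparison of both conditions passed camera and fry. With groups of 3, single samples were not screened.

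The HIF targets had a median log2 change of 0.54 in hypoxia and -0.17 in oscillatory hypoxia, and a direct median difference of -0.62 (oscillatory hypoxia minus hypoxia; fry adjusted p = 9.23e-05). Glycolysis genes stood at 0.42 and -0.15, with a direct difference of -0.49 (fry adjusted p = 0.00102). NF-kB targets and cytokines stood at -0.16 and 0.37, with a direct difference of 0.37 (fry adjusted p = 0.0125). Interferon response genes stood at -0.23 and 0.18, with a direct difference of 0.63 (fry adjusted p = 6.81e-05). Heat shock genes stood at -0.18 and 0.34, with a direct difference of 0.79 (fry adjusted p = 0.00865), which was 0.52 without oscillatory hypoxia replicate 3. With an estimated correlation the camera adjusted p of these 5 lists ranged from 0.234 to 0.834.

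The pattern that a biologist would most want to follow up is in the HIF targets: of 27, 17 rose in hypoxia, 12 rose with lactate, where the list did not pass camera (adjusted p = 0.0642), and 0 rose in oscillatory hypoxia with limma (3 adjusted over the list alone), although 281 genes of any kind were higher in both low-oxygen conditions. For the difference between oscillatory hypoxia and hypoxia, scaling to a total in which mitochondrial genes weigh heavily is argued against, since without those genes in the total the median difference of the HIF targets between oscillatory hypoxia and hypoxia was -0.66. An exchange of the oscillatory hypoxia and lactate labels cannot be told apart from a true effect of the labelled conditions. No gene in the tables marks lactate or oscillation independently of the labels. The correlation of 0.91 between hypoxia and lactate lies above the 0.55 between hypoxia and oscillatory hypoxia. It lies below the highest simulated value of unchanged groups, 0.92. That simulation cannot decide the question, since its groups did not respond (covariance 0.012 against 0.203 here). A label exchange and a lactate effect that resembles hypoxia could each give a correlation of 0.91. A true response of these cells to lactate, or to harvest in a phase of high oxygen, stays open and was not tested.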

How the results depend on the processing

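Sample weights, voom, the rescaling without mitochondrial genes and the list tests without a replicate were chosen after seeing the data. No gene called in a comparison was called in the opposite direction under any alternative. For the other results below the cause was not tested, except where fewer genes or samples entered. The sample weights did not converge fully.

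Median-of-ratios scaling gave 2542 genes higher in hypoxia and 1185 higher in oscillatory hypoxia than in control, and 51 higher and 122 lower in lactate than in hypoxia. Quantile normalization gave 2826, 1224 and, for lactate against control, 2726 higher, 2442 lower in oscillatory hypoxia than in hypoxia, and 60 higher and 119 lower in lactate than in hypoxia. Voom gave 2545 and 1219 higher in hypoxia and oscillatory hypoxia, and 96 and 143 for lactate against hypoxia. Without mitochondrial genes in the total, the last comparison had 34 and 50. Without a filter it had 1 and 0 (17077 genes tested), and with a mean of at least 5 TPM 25 higher. With only the 2 groups compared, the counts were 162 higher and 445 lower for oscillatory hypoxia against control, 2885 higher for lactate against control, 832 and 591 for oscillatory hypoxia against hypoxia, and 77 and 109 for lactate against hypoxia. Sample weights gave 2452 and 4739 for hypoxia, 772 lower for oscillatory hypoxia, 3863 and 3672 for lactate, 745 lower for oscillatory hypoxia against hypoxia, and 3457 and 509 for lactate against hypoxia. The added 2-fold limit left 144 higher and 395 lower genes for hypoxia, 64 and 89 for oscillatory hypoxia and 110 and 303 for lactate against control, 210 and 91 for oscillatory hypoxia against hypoxia, and 4 and 6 for lactate against hypoxia.

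The same replicate numbers occur in every group, but residuals of same-numbered samples correlated at -0.31 to 0.19, which shows no clear pairing by number. With groups this small a weak pairing could be missed. With the replicate number as a block, lactate against hypoxia had 6 higher and 15 lower genes, and the other counts of genes and lists moved by less than 1.5 times.

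Leaving out 1 sample moved the number of genes higher in oscillatory hypoxia than control to 208 to 624 and lower to 630 to 2434, higher in lactate than control to 1198 to 2156, higher in oscillatory hypoxia than hypoxia to 1143 to 2067, and higher and lower in lactate than hypoxia to 0 to 234 and 0 to 101.

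With camera and an estimated correlation 0 lists passed in each of the 5 comparisons. Fry passed 3 lists for oscillatory hypoxia against control and 0 for lactate against hypoxia. Leaving out hypoxia replicate 3 or oscillatory hypoxia replicate 3 gave 7 to 12 lists for lactate against control. The ER chaperone list of oscillatory hypoxia against control had a camera adjusted p of 0.00316 without the first and 0.686, in the lower direction, without the second. For the genes named and the single lists, other settings left 5511 gene and 695 list results on their side of the threshold, while 259 and 89 lost a call and 93 and 21 gained one. Leaving out a sample left 4936 and 248, lost 502 and 4 and gained 46 and 17. Depth was 16413909 to 23443323 reads. With 3 samples per group, 46% to 57% of simulated 1.41-fold changes were recovered, so smaller changes can be missed. That simulation gave all groups equal spread and did not vary depth.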

Other observations

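The tests here of read depth, of shared gene spans, including the choice of its 7 gene lists, and of other splits of the samples were chosen after the result was seen, while the search for genes found only in oscillatory hypoxia replicate 3 was set out before its count was seen.

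Some genes differed in oscillatory hypoxia from both control and hypoxia. Against control and against hypoxia alike, 146 genes were higher and 255 lower, and in 119 and 201 of these all 3 samples lay beyond all 9 samples of the other groups. Part of that separation follows from the choice, since these genes were picked for differing from control and hypoxia. Oscillatory hypoxia was not tested against lactate. Of the genes named here, MAGEB2 and SCG2 were chosen after their values were seen, while CSPG4 was picked by the fixed rule for named genes. The melanoma antigen gene MAGEB2 was at 3.27 to 6.81 TPM, against 0.121 TPM or less elsewhere. SCG2, a secretogranin gene, was at 7.29 to 11.1 TPM, against 2.32 to 4.76 TPM elsewhere. Lower genes included CSPG4, a surface proteoglycan, at 11.8 to 19.7 TPM, against 25 to 49.6 TPM elsewhere. Log2 changes against control and against hypoxia were 1.53 and 1.19 for SCG2, and -1.62 and -0.94 for CSPG4. In SCG2 and CSPG4 hypoxia thus lay between control and oscillatory hypoxia. In MAGEB2, with log2 changes of 2.39 against control and 2.45 against hypoxia, it did not.

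ALPP, a placental alkaline phosphatase gene with near-identical copies, was at 27.9, 25.2 and 96.2 TPM in hypoxia and at 290, 373 and 345 TPM in oscillatory hypoxia.

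Stress genes were far higher in oscillatory hypoxia replicate 3 than in the other replicates of that group: HSPA1A was at 3160 TPM against 222 and 243 TPM, and DNAJB1 at 551 TPM against 107 and 104 TPM, both chosen after their values were seen. Fewer reads are not the reason, since this sample had 20339335 reads against 17392170 and 17016021. RNA of other cells could bring transcripts absent elsewhere. In this sample 0 genes were at 10 TPM or more while under 0.1 TPM in every other sample. Other samples had 0 or 1 such genes. The limit is strict, since in a short gene 1 read elsewhere can exceed 0.1 TPM. Cells that express the same genes as these would add none, so RNA of other cells is not excluded. No biological explanation was tested, because the labels do not say how this sample differed.

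Genes that every cell uses were listed at or near 0. A candidate explanation is that reads in a span shared with another gene were left uncounted: in the lists of ribosomal, respiratory chain, TCA cycle, glycolysis, heat shock and cell cycle genes, 100% of the 19 genes with at least 95% of the span inside other genes were below 1 TPM, against 1.4% of the 147 genes with no overlap. Silence of such genes as a class is argued against by that 1.4%, though a single gene may still be silent. SDHA, with 0% overlap by genes of the table, is 1 of 2 genes without overlap that were below 1 TPM. Of 71 list genes with partial overlap, 2 were below 1 TPM. Outside these lists, LDHB had a mean of 0.0526 TPM with 18.3% of its span inside other genes. Spans shared with genes of the table therefore do not account for every such gene. Overlap with genes outside the table was not measured, so shared spans as such are not excluded for SDHA and LDHB. CDKN2A was listed at 0 with 100% of its span inside other genes, so its state stays open. SDHA and CDKN2A were chosen after their values were seen.

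For the counts of called genes, the 6 samples of each comparison can be split in 10 ways, and in each comparison only 1 split, the real one, gave as many genes. That is too few splits for a share under 0.05. The real split gave 4404 genes for hypoxia against control (highest other 0), 1845 for oscillatory hypoxia (0), 3930 for lactate (1), 3205 for oscillatory hypoxia against hypoxia (30) and 37 for lactate against hypoxia (1).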
